A study of Caenorhabditis elegans with 2 samples.

How the data were processed

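NHR-11 tagged with eGFP was profiled by ChIP-seq in whole L4 larvae of mixed sex, in 2 biological replicates that the labels number 1 and 2. The labels give them as separate biological samples of the same strain, and name no batch or date of growth. Per the texts deposited with the files, each replicate's list of peaks and background regions was called on that replicate's alignments together with a further file that was also used for a control-normalised signal. How that file entered the calling is not stated. The pooled list was called on both replicates' alignments together with such a file, and the thresholded list was derived from the pooled list and both replicate lists by irreproducible discovery rate (IDR). The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. A control experiment that the labels name as possible was not used here, so no comparison with untagged animals or input DNA was made beyond what the authors' peak calling may hold. Every list was deposited in builds ce11 and ce10, and the analysis used ce11, with ce10 as an alternative and no conversion between them.

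The deposited signal value of a peak is a strength given by the authors' peak caller, on a scale that is not stated. The deposited −log10 q values of the pooled list reached a maximum of 3.525 that 1675 peaks shared, so peaks were ranked by signal. The deposited summit offset gave each summit's position, and coordinates are given counting from 1. All 2719 thresholded peaks were in the pooled list with the same values, and they were exactly its peaks with a signal of 54.9 or more, so the thresholded list is the upper 20.1% of the pooled list. Most thresholded peaks (2655) were 376 bp wide. The lists give no read counts, so the depth per library is unknown and no floor from counts could be set.

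Both builds held nearly the same peaks, with 2718 thresholded peaks in ce10 and 2719 in ce11. In the same order, the pooled lists held 13600 and 13558, replicate 1 lists of 19081 and 19074 and replicate 2 lists of 22134 and 22137. Signal values sorted within each list differed by at most 1.07%. Genes came from Ensembl release 115 for WBcel235, which has the sequence of ce11, with 19973 protein-coding genes on 6 chromosomes. As checks of the build, no peak ran past a chromosome's end, and 99.9% of 31805 annotated start codons read ATG in the genome sequence.

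A thresholded peak counted as found in a replicate when its interval held a summit of that replicate's 2719 strongest peaks. The share found in both was given without a test, since the thresholded list was derived with both replicate lists. The planned 1000 circular shifts along each chromosome were used instead on each replicate's own peaks against the other replicate's list, a comparison chosen after the data were seen. Summits were assigned to promoters (1000 bp upstream to 200 bp downstream of a protein-coding gene's annotated start) and then, in order, to 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic sequence, and compared with 10000 sets of random positions drawn on the same chromosomes, over all summits and, chosen after the data were seen, over those outside promoters alone. Chromosome shares were compared with length by exact binomial tests. For 24 gene lists, of which 6 were markers of tissues, members with a summit in the promoter window were compared with all other protein-coding genes by Fisher's exact test. Genes of 8 noncoding classes counted as having a peak with a summit within 500 bp. For 18 motifs and all 6-mers, windows within 50 bp of each summit were compared with windows 300 to 400 bp away, on a side drawn at random, by an exact McNemar test. The 679 strongest and 679 weakest peaks were compared by Fisher's exact test. P values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05, and shares carry 95% Clopper-Pearson intervals. Neighbouring peaks and genes are not independent, so p values of these tests describe these lists and not a population of animals. Tests were 2-sided unless one-sided is stated.

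Lists, motifs, tests and most alternatives were fixed before the data were examined. Named genes were the nearest protein-coding gene of each of the 25 strongest thresholded peaks, nhr-11 and unc-119, up to 4 members with the strongest promoter peak in each list or noncoding class past the threshold, and up to 4 of each tissue marker list. The muscle genes pat-10, unc-120 and myo-3 and the genes named with the weaker peaks fall outside that rule and were chosen after their values were seen. Some members that the rule takes are left unnamed for brevity, among them piRNA genes, and tRNA genes and pseudogenes that carry only identifiers. The gene mnk-1 was chosen after its values were seen. Alternatives covered the overlap and number of peaks matched, the promoter window and starts, the middle of the peak, the stronger 1359 peaks, each replicate's own list without the other replicate, gene number as background, the length of the upstream intergenic space, nearest starts, noncoding distance, motif windows and flanks, and build ce10. GC content as a covariate for gene lists and as a match for motif windows was added after the data were seen, as were a logistic model without a covariate and one with the upstream length in classes (no space, and 10 equal parts of the other genes).

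The tests were run on simulated data with fixed seeds. Over 20 sets of 2719 random positions, p was under 0.05 in 0 of 20 promoter tests, 2 of 140 class tests, 6 of 160 noncoding tests and 17 of 360 motif tests, and 0 of 10400 6-mer tests in 5 sets passed after adjustment. Over random genes, 3 of 2400 list tests passed after adjustment, and with the length classes 0 of 480 did over 20 sets of genes drawn by upstream length. A list's share was also raised 4-fold. It was called in 99 of 100 runs for 81 ribosomal protein genes, 88 of 100 for 38 respiratory chain genes and 21 of 100 for 13 muscle markers, so short lists could be missed. A forkhead site written into 3% of windows was called in 20 of 20 sets, and replicate lists sharing no peaks by design passed in 1 of 20. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.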

Results

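The series was made to map where NHR-11, a member of the nuclear hormone receptor family of transcription factors, is bound along the genome of Caenorhabditis elegans. Chromatin immunoprecipitation followed by sequencing (ChIP-seq), which recovers the DNA attached to a chosen protein, was run on whole larvae at the L4 stage, the last larval stage of the worm. The animals came from a transgenic strain in which NHR-11 carried a green fluorescent protein tag (eGFP). A single group with 2 biological replicates was analysed, and no conditions were compared. The data answer which genes and regions carried peaks and how well the replicates matched. No control ChIP was used here beyond what the authors' peak calling may hold, so peaks particular to NHR-11 cannot be told apart from others. The deposited peak lists hold no read counts, so the depth of each library is unknown, and the intervals given here cover the counting of peaks or genes only. In build ce11, the list of replicate 1 held 19074 peaks and background regions, that of replicate 2 held 22137, and the list called on both replicates pooled held 13558. The authors' thresholded list, which rests on the reproducibility of peaks between replicates, held 2719 peaks. Each peak's signal value is the authors' own and is used here only to describe and rank peaks within a list.

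The highest signal of the thresholded list stood on chromosome II at 10563588, 181 bp upstream of cdc-48.1 (WBGene00007352), which encodes an AAA ATPase that unfolds ubiquitinated proteins. Its signal value was 1108, and it was also first in both replicates' own lists, with signal values of 539 and 571. Ribosomal protein genes had the nearest start for 6 of the 25 strongest peaks. The first was rpl-3 on III (summit 3867584, 270 bp upstream of the start, signal 683). The others were rpl-15 on IV (654919, 343 bp upstream, signal 500.3), rps-1 on III (4475652, signal 436), rpl-11.2 on X (2242973, signal 408.4), rpl-35 on III (7854686, signal 407.8) and rpl-12 on IV (13240686, signal 370). At 2 more of these peaks a ribosomal protein gene shared the peak with the nearest gene. The peak on IV at 4750064 lay 176 bp upstream of Y17G9B.5 and 286 bp upstream of rpl-20 (signal 499.6). That on III at 5679148 lay 143 bp upstream of ska-3 and 150 bp upstream of rps-12 (signal 484).

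Other genes nearest to the 25 strongest peaks included iff-2 on II, a homologue of translation factor eIF5A (summit 8561437, 70 bp upstream, signal 631), and drr-2 on III, related to initiation factor eIF4H (13643741, 171 bp upstream, signal 377). Also among them were hsp-1 on IV, a constitutive Hsp70 chaperone (17278591, 368 bp upstream, signal 387), and his-37 on V, a histone H4 gene (9547008, 97 bp upstream, signal 544). The list also held tasp-1 on III (10759263, 44 bp upstream, signal 646), puf-9 on X, a Pumilio-type RNA-binding protein (5841301, 291 bp upstream, signal 549.8), tag-340 on III (4899922, signal 459), tos-1 on V (9344305, signal 405) and nspc-17 on X (14525927, signal 380.3). For a pair of the strongest peaks the nearest start was that of another nuclear hormone receptor gene. The summit on II at 9603648 (signal 621) lay in an intron of nhr-19, 1878 bp downstream of its start. The summit on V at 13869742 (signal 683) was intergenic, 3051 bp downstream of the start of nhr-175 and beside an annotated pseudogene (13869888 to 13872529).

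Of the 25 summits, 18 lay in a promoter window, 16 of them within 500 bp upstream of the nearest start. A further 6 lay over 2000 bp from the nearest protein-coding start, with a single annotated start taken per gene. Those 6 included the second strongest peak, an intergenic summit on III at 4237912 (signal 728, 4663 bp from the start of F43C1.7), intergenic summits nearest to C30E1.4 (X, 16929766) and K02D3.1 (X, 13700888), and a summit in an intron of mom-1 that was nearest to cest-16 (X, 6296557). The summit assigned to cmd-1, the calmodulin gene, lay 4801 bp upstream of it, inside the long noncoding RNA gene linc-128 (V, 1151470, signal 476). All 25 were found in both replicates, at rank 42 or better in replicate 1 and rank 33 or better in replicate 2.

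Most thresholded peaks were among the strongest of both replicates. Of the 2719 thresholded peaks, 1986 (73.0%, 95% exact Clopper-Pearson interval 71.3 to 74.7) held a summit among the 2719 strongest peaks of each replicate. Replicate 1 had such a summit in 85.8% of them and replicate 2 in 86.0%. Of the 2719, 348 were found with replicate 1 only, 353 with replicate 2 only and 32 with neither. With the full lists of both replicates the share was 99.3%, and among the stronger 1359 thresholded peaks it was 98.7%. Peaks near the limit of 2719 can fall outside it in either list. The thresholded list was itself derived with both replicate lists and equals a cut on the pooled signal. These shares therefore cannot show a trend with strength. Compared directly, 73.5% (interval 71.8 to 75.2) of the 2719 strongest peaks of replicate 1 held a summit of the 2719 strongest of replicate 2, and 96.9% held one of its full list. In the other direction these shares were 73.7% (interval 72.0 to 75.4) and 95.8%. Circular shifts along the chromosomes gave at most 1.91% for the strongest peaks and 9.67% for the full lists (n = 2719 peaks, one-sided permutation p = 0.001 in each case, the smallest that 1000 shifts can give). Over the 2700 peaks matched in both full lists, the ranks of the signal values correlated with Spearman's rho of 0.67, and over the 1356 matched among the stronger ones with 0.69. This value describes peaks, which are not independent replicates, and peaks near the threshold were selected on the pooled signal.

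**Figure D1:**
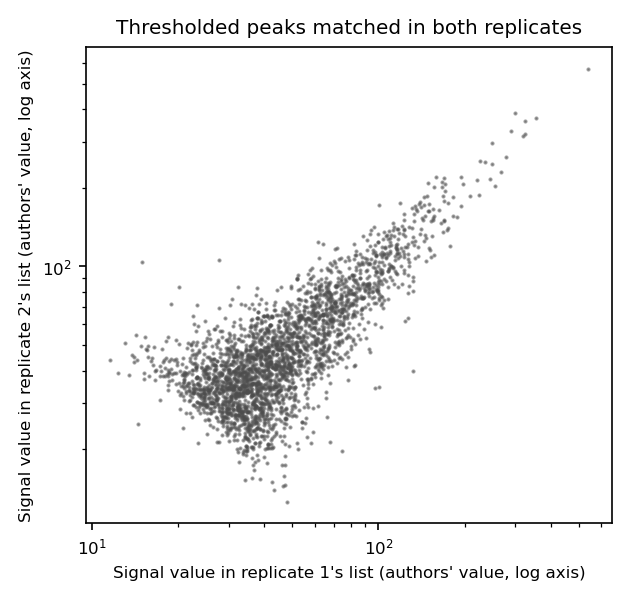
Signal value of each matched thresholded peak in the list of replicate 1 (x axis, log scale, authors' unit) against that in the list of replicate 2 (y axis, log scale). Each point is 1 of 2700 peaks; the point at the upper right is the cdc-48.1 peak, at 539 and 571.

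Genes for protein synthesis carried peaks at their promoters far more often than other genes. Of 81 ribosomal protein genes, 64 (79.0%, interval 68.5 to 87.3) had a thresholded summit between 1000 bp upstream and 200 bp downstream of the start, against 7.99% of all other protein-coding genes. All 64 had their strongest such summit upstream of the start, at a median of 293 bp, and 45 of them carried one of the 679 strongest peaks. Translation factors followed, with 14 of 33 genes (42.4%). They were led by iff-2, eef-1G on V (summit 10965682, 37 bp upstream, signal 345), eef-1A.2 on X (7823294, signal 326) and eef-1A.1 on III (6972111, signal 298), subunits of the elongation complex that delivers aminoacyl-tRNA. Odds ratios against all other protein-coding genes were 43.3 for ribosomal proteins (adjusted p = 1.41e-52) and 8.22 for translation factors (adjusted p = 7.35e-07; 2-sided Fisher exact tests, Benjamini-Hochberg over 24 lists). With each summit given to the nearest start alone the odds ratio of ribosomal proteins was 13.6 and stayed past the threshold (adjusted p = 1.99e-23, Fisher exact test).

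Genes for energy supply and protein turnover were also over-represented. Peaks stood at 12 of 38 genes of the respiratory chain and ATP synthase (31.6%, interval 17.5 to 48.6, Fisher exact test, adjusted p = 0.000141). Among them were cox-5B on I (9788703, 22 bp upstream, signal 336), cox-5A on III (12905201, signal 319.7), atp-1 on I (12652283, signal 256) and atp-2 on III (5228171, signal 190.4). Of 33 proteasome subunit genes, 11 had a peak (33.3%, interval 17.96 to 51.8, Fisher exact test, adjusted p = 0.000145). The strongest was at rpn-3 on III (8447162, signal 310.3), with rpt-2, rpn-5 and rpn-11 at signals of 95.8, 87.6 and 84.8. Heat shock proteins had a peak at 6 of 22 genes (27.3%, interval 10.7 to 50.2, Fisher exact test, adjusted p = 0.0180). The strongest were hsp-1, hsp-110, hsp-3 (X, 6092144, signal 222) and hsp-60 (III, 1619160, signal 206). The summit of hsp-110 was the same as that of rpn-3. Vacuolar ATPase genes, which encode the proton pump of acidic organelles, had a peak at 5 of 20 genes (25%, interval 8.66 to 49.1, Fisher exact test, adjusted p = 0.0419), the strongest at vha-8 (IV, 6790615, signal 226) and vha-12 (X, 4190769, signal 194). The vacuolar ATPase odds ratio was 3.70, and its call was lost in Fisher exact tests at similar odds ratios with the narrower promoter window (3.65, adjusted p = 0.0786) and with nearest starts only (3.74, 0.0804), and in logistic models over n = 19973 genes, chosen after the data were seen, with GC content (3.50, adjusted p = 0.0568) and with classes of the upstream length (3.34, 0.0716). That of heat shock proteins, 4.17, was 3.37 without replicate 2 (Fisher exact test, adjusted p = 0.0605) and 2.36 with nearest starts only (0.290).

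Large families of environmental and defence genes carried fewer peaks than other genes. Chemoreceptor genes had a peak at 11 of 1293 promoters (0.851%, interval 0.425 to 1.52, Fisher exact test, adjusted p = 4.16e-34). The strongest were at sri-5 (I, 11182554, signal 143), srh-269 (V, 16592323, signal 108), srh-16 and srj-1. In Fisher exact tests too, C-type lectins had 1 of 240 (0.417%, clec-149 on III, adjusted p = 3.38e-07) and F-box A proteins 2 of 170 (1.18%, fbxa-90 and fbxa-153 on V, adjusted p = 0.000339). With so few peaks their odds ratios of 0.0458 and 0.131 moved with the replicate used. For C-type lectins the odds ratio was 0.0459 without replicate 1 and 0.0950 without replicate 2. That of F-box A proteins was 0.0652 without replicate 1 and 0.135 without replicate 2. Collagens of the cuticle had 4 of 156 (2.56%, col-38, col-185, col-2 and col-63, Fisher exact test, adjusted p = 0.0139), a call lost without replicate 2 (odds ratio 0.535 in place of 0.290, adjusted p = 0.252). Detoxification enzymes had 6 of 185 (3.24%, Fisher exact test, adjusted p = 0.0220), led by cyp-13A2 (II, 9787578, signal 134.4) and gst-27 (II, 15166055, signal 100.4). By the same exact test the odds ratio of 0.369 rose and the call was lost without replicate 1 (0.4998, adjusted p = 0.108), among the stronger 1359 peaks (0.457, 0.307), with the narrower window (0.486, 0.175) and with nearest starts only (0.498, 0.187).

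**Figure D2:**
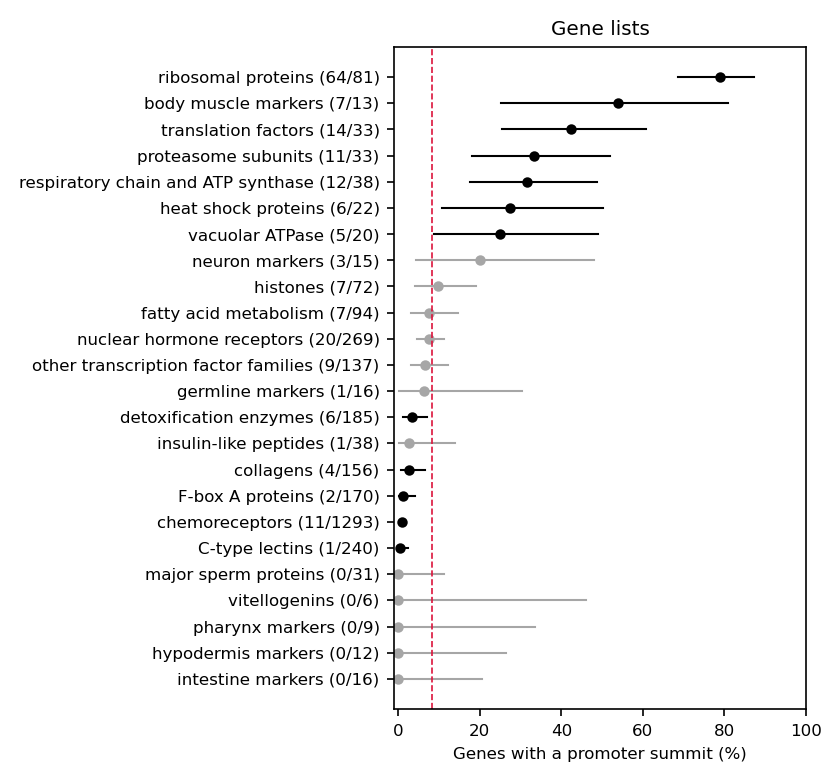
Share of each gene list's members with a thresholded summit in the promoter window (x axis, percent; members with a peak and members in all are given beside each name), with 95% Clopper-Pearson intervals as lines. Black marks lists past an adjusted p of 0.05 and grey the others; the dashed red line is the share over all protein-coding genes, 8.28%, and ribosomal proteins stand at 79.0%.

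The remaining lists did not pass the threshold. Nuclear hormone receptors, the family of NHR-11 itself, had a peak at 20 of 269 promoters (7.43%, interval 4.60 to 11.2, Fisher exact test, adjusted p = 0.885), and members of other transcription factor families at 9 of 137 (6.57%, adjusted p = 0.840). In the same Fisher exact tests, fatty acid metabolism had 7 of 94 (7.45%, adjusted p = 1), histones 7 of 72 (9.72%, adjusted p = 0.840), insulin-like peptides 1 of 38 (adjusted p = 0.590), major sperm proteins 0 of 31 (adjusted p = 0.199) and vitellogenins, the yolk proteins, 0 of 6 (adjusted p = 1). Histones passed as lower when the GC content of the promoter window entered a logistic model over n = 19973 genes, chosen after the data were seen (odds ratio 0.341 in place of 1.19, adjusted p = 0.00568). Major sperm proteins passed as lower in the logistic model without any covariate (n = 19973 genes, adjusted p = 0.0411), so that call came with the change of test.

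Among markers of tissues, only those of body wall muscle passed the threshold with the promoter window used here. Peaks lay at 7 of 13 muscle genes (53.8%, interval 25.1 to 80.8, odds ratio 12.97, adjusted p = 0.000139 in the Fisher exact test, 0.000174 when adjusted over the 6 tissue lists alone). These genes were mup-2, a troponin T (X, 6410566, 339 bp upstream, signal 95.6), act-4, an actin (X, 4960609, signal 87.1), hlh-1, the myogenic MyoD homologue (II, 4518464, signal 81.5), unc-89, a giant muscle protein (I, 4035624, signal 81.3), pat-10, unc-120 and myo-3. Their signals lay between 58.4 and 95.6, and none was among the 679 strongest peaks. Markers of intestine (0 of 16, interval up to 20.6%), hypodermis (0 of 12, up to 26.5%) and pharynx (0 of 9, up to 33.6%) had no promoter peak. Germline markers had 1 of 16, cgh-1 (III, 7498588, signal 154), and neuron markers 3 of 15, egl-21, ric-19 and snb-1 (signals 82.3, 81.8 and 65.0). In Fisher exact tests between lists, muscle markers differed from those of intestine (adjusted p = 0.00550), hypodermis (0.0130), germline (0.0162) and pharynx (0.0209) but not from those of neurons (0.114; Benjamini-Hochberg over 5 pairs). These pairs of lists were compared after the shares were seen. By Fisher exact tests the muscle call was lost among the stronger 1359 peaks (odds ratio 3.79, adjusted p = 0.256), its odds ratio was 6.96 without replicate 1 and 25.9 without replicate 2, and with the wider promoter window neuron markers also passed (odds ratio 5.16, adjusted p = 0.0108).

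Genes of 4 small noncoding RNA classes and of lincRNAs were frequent neighbours of peaks, while piRNA genes were rare ones. Summits lay within 500 bp of 79 of 346 snoRNA genes (22.8%, interval 18.5 to 27.6, against 3.09% for random positions), 102 of 612 tRNA genes (16.7% against 3.06%), 29 of 194 lincRNA genes (14.9% against 5.94%), 25 of 261 miRNA genes (9.58% against 3.05%) and 11 of 129 snRNA genes (8.53% against 2.75%). The strongest peak at a snoRNA was the rps-12 peak, beside F54E7.10, and the strongest at a tRNA gene lay on X at 8036397 (signal 275). The 4 strongest peaks at snRNA genes lay at sls-2.4 (I, 4172163, signal 351), sls-2.2 (II, 5543558, signal 317), sls-2.1 (II, 5844803, signal 307) and sls-2.8 (III, 12250406, signal 199), genes of the SL2 RNA that is spliced onto downstream messages of operons. Of the 111 other snRNA genes 5 had a summit (4.50%, interval 1.48 to 10.2). That interval holds the 2.75% of random positions for the whole class, so no excess was shown without the SL2 genes. Peaks at miRNA genes were led by mir-5549, which shared the peak of eef-1A.1, and mir-53 (IV, 11027805, signal 189). Pseudogenes (27 of 2128, 1.27% against 6.02%) and piRNA genes, the largest class (130 of 15363, 0.846% against 2.22%), were under-represented, and 0 of 20 rRNA genes had a summit (interval up to 16.8%). Adjusted p was between 0.00032 and 0.00457 for the 7 classes that passed (2-sided randomisation with 10000 sets, Benjamini-Hochberg over 8 classes). Within 100 bp the miRNA call was lost (1.53% of n = 261 genes, adjusted p = 0.427). Random positions were drawn over whole chromosomes and not matched on the excess of summits in coding promoters (47.8% against 21.1%). That excess can raise the shares of noncoding genes that lie near coding starts, and its part was not tested.

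Summits gathered just upstream of protein-coding genes. Promoter windows held 1300 summits (47.8%, interval 45.9 to 49.7) against 21.1% ± 0.788 (SD) of random positions on the same chromosomes (n = 2719 summits, p = 0.0002, the smallest that 10000 sets can give, 2-sided). Coding exons held 22 summits (0.809% against 19.8% at random) and 3′ UTRs 17 (0.625% against 2.42%), both fewer than random positions. Other exons, a class that joins those of pseudogenes and of noncoding genes except piRNAs, held 159 (5.85% against 2.65%). Each of these classes had an adjusted p of 0.00028 over 7 classes. The excess in other exons was not split by kind of gene, and pseudogenes had few summits within 500 bp (1.27% against 6.02% at random). Classes were assigned after promoters, whose excess lowers the share left to the others, so the 1419 summits outside promoters were also compared with random positions outside them, a comparison chosen after the data were seen. There introns held 551 (38.8%, interval 36.3 to 41.4, against 38.1%, adjusted p = 0.609 by randomisation, n = 1419 summits), in place of 20.3% against 30.3% (adjusted p = 0.00028) over all summits. Intergenic positions held 639 (45.0%, interval 42.4 to 47.7, against 29.4%, adjusted p = 0.0003, n = 1419 summits) and 5′ UTRs 31 (2.19% against 1.06%, adjusted p = 0.00096), neither of which passed over all summits (23.5% against 22.9%, adjusted p = 0.472, and 1.14% against 0.829%, adjusted p = 0.125; n = 2719). Coding exons (1.55% against 24.9%) and 3′ UTRs (1.198% against 3.08%) stayed lower and other exons (11.2% against 3.38%) higher (adjusted p = 0.0003 for each, n = 1419 summits). Without replicate 2, 5′ UTRs also passed over all summits (1.32% of n = 2719 summits, adjusted p = 0.0114). With the starts of all transcripts of protein-coding genes, promoter windows held 1509 summits (55.5% against 25.85% of random positions). Some of the 1419 summits outside the windows used here therefore lay at other annotated coding starts. The nearest start was at a median of 852 bp from a summit and 1597 bp from a random position.

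**Figure D3:**
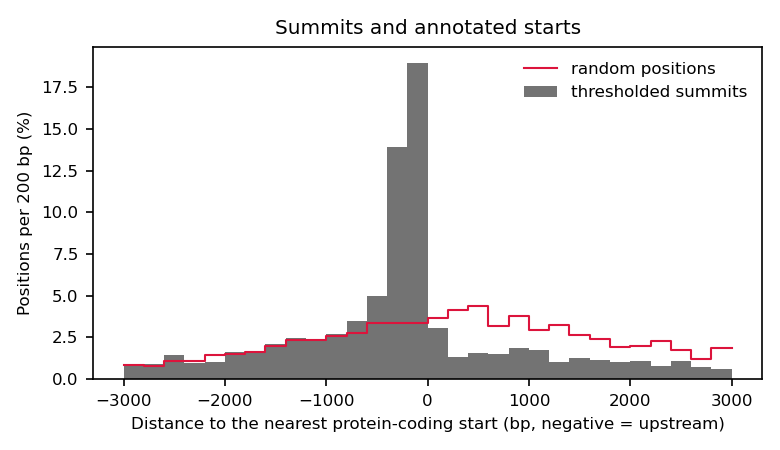
Distance from each thresholded summit to the nearest protein-coding start (x axis, bp, negative values upstream) and percent of positions per 200 bp (y axis). Grey bars are the 2719 summits and the red line an equal number of random positions; 35.8% of summits and 8.50% of random positions lay within 500 bp upstream.

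Chromosome X carried more peaks than its length and chromosomes IV and V fewer. X held 575 of the 2719 peaks (21.1% against 17.7% of the genome's length, adjusted p = 6.50e-06, exact binomial test). By the same exact test V held 417 (15.3% against 20.9%, adjusted p = 1.37e-12) and IV held 380 (13.98% against 17.5%, adjusted p = 3.16e-06; Benjamini-Hochberg over 6 chromosomes). I (17.1% against 15.03%) and III (15.8% against 13.7%) were above their length at an adjusted p of 0.00314, and II at 0.0454 (16.6% against 15.2%). By the exact binomial test the excess on I was lost without replicate 1 (adjusted p = 0.198) and that on II without replicate 2 (0.115), and both were lost among the stronger 1359 peaks (0.239 and 0.158). Against the share of protein-coding genes in place of length, II was below its share and not past the threshold (adjusted p = 0.388, exact binomial test).

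Of the 18 motifs, GAGAGA repeats were the most enriched at summits, and the nuclear receptor core sequence did not pass the threshold. RGGTCA, a core sequence that many nuclear receptors bind, lay within 50 bp of 130 summits (4.78%, interval 4.01 to 5.65) and in 4.30% of windows 300 to 400 bp away at the same peaks, a ratio of 1.11 (exact McNemar test, adjusted p = 0.461). By the same exact test it passed the threshold within 100 bp of the summit (ratio 1.2, adjusted p = 0.0373) and against flanks at 800 to 900 bp (ratio 1.35, adjusted p = 0.0312), and lay below 1 (0.813, adjusted p = 0.130) against windows matched on GC content. The relaxed form RGKTCA was rarer at summits than in flanks (10.63% against 13.4%, exact McNemar test, adjusted p = 0.00326), and lost that call with a 25-bp window (adjusted p = 0.0666) or farther flanks (0.0913). GAGAGA repeats lay at 827 summits (30.4%, interval 28.7 to 32.2, against 5.55%, ratio 5.48, exact McNemar test, adjusted p = 8.73e-127). The E-box CACGTG (5.995% against 1.99%, adjusted p = 5.09e-14), any E-box (43.5% against 30.0%, adjusted p = 3.58e-24) and the E2F type site (8.02% against 2.98%, adjusted p = 3.57e-16) were also more frequent (exact McNemar tests, Benjamini-Hochberg over 18 motifs).

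Summit windows had a GC content of 46.1% and their flanks 34.9%, and calls of GC-rich or AT-rich motifs changed against windows matched on it. The Sp1 type site (5.59% against 1.47%, ratio 3.80) and runs of C (3.53% against 0.883%, a ratio of 4) were higher at summits. The TATA box (5.08% against 13.3%), runs of T (21.4% against 41.8%), the SKN-1 site (2.94% against 4.74%), the heat shock element (3.604% against 7.06%) and TGATAA (7.17% against 9.86%) were lower, with adjusted p of 0.0011 or less for each. Against windows of the nearest GC content 200 to 2000 bp away (45.6% GC), an alternative chosen after the data were seen and tested in the same exact way, calls ended for Sp1 (ratio 1.21, adjusted p = 0.163), runs of C (1.22, 0.277), the TATA box (0.965, 0.851), runs of T (1.02, 0.845) and SKN-1 (0.976, 0.936), and TGATAA turned higher (1.34, adjusted p = 0.0109). GAGAGA (ratio 3.36), CACGTG (1.87), the E2F site (1.46) and any E-box (1.17) stayed higher there, and the heat shock element (0.636) and RGKTCA (0.734) stayed lower. The matched windows were chosen by GC content and distance, not by genomic class, and summits were rare in coding exons (0.809% against 19.8% at random). Changes with GC matching therefore cannot be told apart from a difference in genomic class. The forkhead site GTAAACA was higher (2.46% against 1.47%, exact McNemar test, adjusted p = 0.0139), but the call was lost without replicate 1 (0.0760), without replicate 2 (0.0935), among the stronger 1359 peaks (0.157) and with another random choice of flank sides (0.0550). It was kept within 25 bp (ratio 2.06), within 100 bp (1.37) and against the farther flanks (1.86), and its ratio rose from 1.68 to 3.19 with GC matching (exact McNemar test, adjusted p = 2.40e-06). GATA cores (19.97% against 19.7%), the PHA-4 site (25.6% against 27.6%), the AP-1 site (1.36% against 0.846%) and the CRE (1.07% against 0.625%) had adjusted p between 0.112 and 0.863. In the same exact test the CRE passed without replicate 2 (ratio 2.50, adjusted p = 0.0112), among the stronger 1359 peaks (4.67, 0.0176), within 100 bp (1.67, 0.0296) and with the other flank sides (2.42, 0.0159). Within 100 bp the AP-1 site passed as higher (1.44, exact adjusted p = 0.0441) and the PHA-4 site as lower (0.906, 0.00108). With GC matching PHA-4 sites (1.34, 8.64e-08) and GATA cores (1.40, 9.10e-08) passed as higher.

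**Figure D4:**
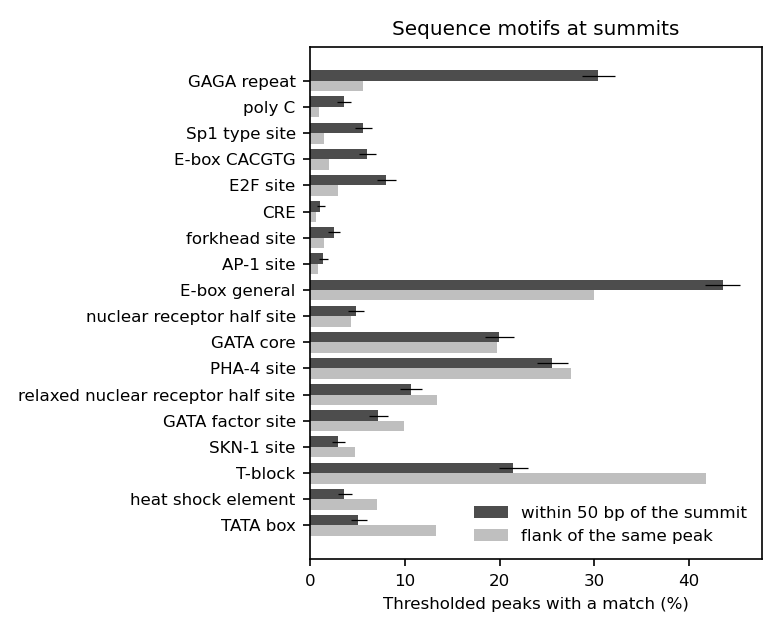
Percent of the 2719 thresholded peaks with a match to each motif (x axis) within 50 bp of the summit (dark bars, with 95% Clopper-Pearson intervals) and in an equal window 300 to 400 bp away at the same peaks (light bars). Motifs are ordered by the ratio of both shares; GAGA repeats stand at 30.4% against 5.55%.

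Over all 6-mers, counted together with their reverse complements, 750 were more frequent at summits and 520 less frequent at an adjusted p under 0.05. Against windows of matched GC content, which were not matched on genomic class, these counts were 280 and 441, so that fewer were called higher than lower. Of the 10 with the largest ratios, ACGCAG (15.9% of summits against 1.80% of flanks, ratio 8.80, exact McNemar test, adjusted p = 3.79e-78), GACGCA (15.5% against 1.77%, ratio 8.77) and AGACGC (14.2% against 1.91%, ratio 7.42) overlapped, and CGTCTC (17.9% against 2.87%, ratio 6.23) extended them on the other strand. Another overlapping pair was GAGCGC (9.71% of summits, ratio 7.76) and AGAGCG (9.64% against 1.47%, ratio 6.55). With GC matching their ratios were lower and still called, at 3.56 for ACGCAG, 3.17 for GACGCA, 3.14 for AGACGC, 2.49 for CGTCTC, 2.59 for GAGCGC and 2.73 for AGAGCG. The 6-mer with the largest ratio, GCTAGC (9.50), lay at only 19 summits and was no longer called against windows of matched GC content (ratio 0.826, exact test, adjusted p = 0.762). The heptamer GACGCAG, counted after these values were seen, lay within 50 bp of 300 summits (11.03%), in 12 flank windows (0.441%) and in 54 windows of matched GC content (1.99%). Its share was 11.5% at summits in promoters and 10.57% at other summits (Fisher exact test, adjusted p = 0.533 over 5 sequences). By the same exact test GAGCGC was more frequent in promoters (14.5% against 5.29%, adjusted p = 1.39e-15) and GAGAGA outside them (34.9% against 25.5%, adjusted p = 3.51e-07).

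Strong peaks lay in promoters more often than weak ones. Of the 679 peaks with the highest signal 56.1% had a summit in a promoter window, against 44.2% of the 679 with the lowest (adjusted p = 9.68e-05, 2-sided Fisher exact test, Benjamini-Hochberg over 14 measures). GAGAGA was more frequent at the strong peaks (34.5% against 28.1%, Fisher exact test, adjusted p = 0.0487), while TGATAA (3.24% against 8.10%, adjusted p = 0.000661) and runs of T (13.99% against 26.5%, adjusted p = 1.60e-07) were more frequent at the weak ones. The other 10 motifs did not pass, with the E2F site nearest to it (9.43% against 5.89%, Fisher exact test, adjusted p = 0.0520).

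The gene of the tagged protein had no thresholded peak nearby. The nearest one lay 73.5 kb from nhr-11 (WBGene00003610, IV, 9070003 to 9073622). Within 20 kb of the gene, the pooled list held 2 peaks, with a best rank of 6505 of 13558, and the lists of replicates 1 and 2 held 1 and 3. At unc-119 (WBGene00006843, III, 10902641 to 10908935), a neuronal gene that is mutated in this strain, 1 thresholded peak lay inside the gene at 10903470, with a signal of 126 and rank 633, and was also in both replicates' lists at ranks 658 and 637.

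The densest stretch of peaks lay over mnk-1, a kinase gene, on chromosome II. In each of the 4 lists the 20-kb bin with the most summits was that from 10540001 to 10560000, with 11 thresholded peaks, 25 pooled peaks, 26 of replicate 1 and 25 of replicate 2. The next densest bins held 8, 21, 20 and 23, and the mean over 5016 bins was 0.542 thresholded peaks. Inside mnk-1 (WBGene00011304, 10542421 to 10555044) lay 6 thresholded peaks, 4 of them in introns, the strongest with a signal of 351.

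**Figure D5:**
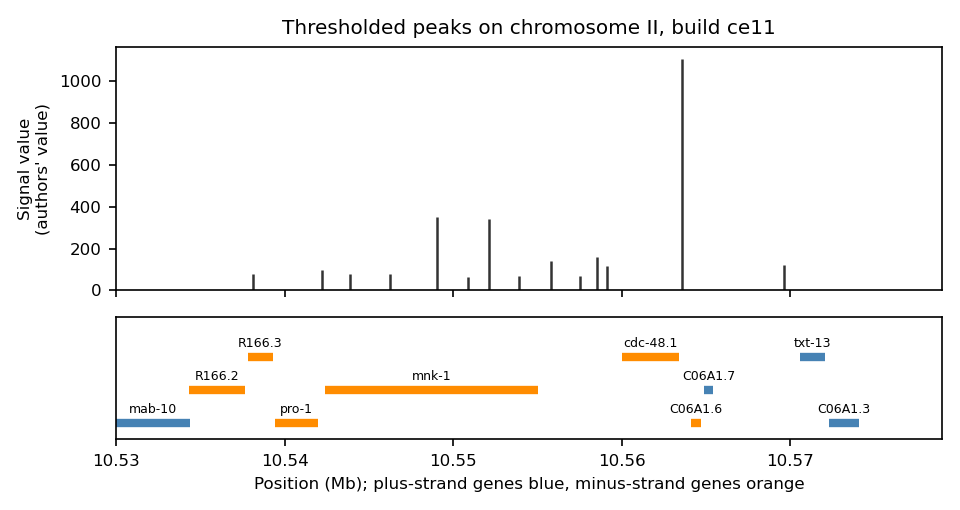
Thresholded peaks around mnk-1 and cdc-48.1 on chromosome II in build ce11: the upper part gives each summit's signal value (y axis, authors' unit) by position (x axis, Mb), and the lower part the protein-coding genes, blue on the plus strand and orange on the minus strand. The tallest line, at 1108, is the peak upstream of cdc-48.1, and 6 lines stand inside mnk-1.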

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

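The weaker peaks of the pooled list, which the thresholded list leaves out, were examined after the main results were seen, as were the tests on them. They are listed here because the report does not describe them. Of these 10839 peaks, 6064 (55.9%, interval 55.0 to 56.9) held a summit of both replicates' full lists. The pooled peaks were called on the same reads as those lists, so a share above that of shifted positions follows from how they were made and is not tested. Between the replicates, 38.8% (interval 38.1 to 39.6) of the 16049 replicate 1 peaks that overlapped no thresholded peak held a summit of replicate 2's list, and 33.7% (interval 33.0 to 34.3) of 19019 the other way. Circular shifts gave at most 8.88 and 7.82% (one-sided permutation p = 0.001 for each, the smallest that 1000 shifts can give). Promoter windows held 30.3% of their summits (interval 29.5 to 31.2), against 21.3% of random positions. The receptor core sequence RGGTCA was more frequent at these summits than in their flanks (5.45% against 4.06%, exact McNemar test, adjusted p = 3.13e-06), but its share did not differ in a Fisher exact test from the 4.78% at thresholded summits (adjusted p = 0.191). These flanks were not matched on GC content. At thresholded summits such matching took the ratio of RGGTCA from 1.11 to 0.813, so its excess at weaker summits may depend on the flanks used. TGATAA was more frequent at weaker than at thresholded summits (10.8% against 7.17%, Fisher exact test, adjusted p = 2.22e-08) and GAGAGA less frequent (13.1% against 30.4%, adjusted p = 6.16e-92).

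Genes that had only weaker peaks in the promoter window included more of fatty acid metabolism (29 of 87 genes without a thresholded peak, 33.3% against 18.5% of other such genes, odds ratio 2.20, Fisher exact test, adjusted p = 0.00592), of nuclear hormone receptors (64 of 249, 25.7%, odds ratio 1.53, adjusted p = 0.0176) and of detoxification enzymes (46 of 179, 25.7%, odds ratio 1.52, adjusted p = 0.0498). Among the strongest were lbp-9 (V, 2068111, signal 53.8), acs-4 (III, 7166869, signal 47.7) and elo-6 (IV, 5388845, signal 45.9), which serve lipid binding, acyl-CoA synthesis and fatty acid elongation, cyp-33B1 (V, 9040441, signal 48.2), nhr-50 (V, 16000598, signal 53.4) and nhr-64 (I, 3101903, signal 51.6). Proteasome subunits (14 of 22, odds ratio 7.70), respiratory chain genes (13 of 26, odds ratio 4.40) and translation factors (8 of 19, odds ratio 3.19) were higher too, and chemoreceptors (odds ratio 0.513), C-type lectins (0.209), histones (0.211) and major sperm proteins (0.146) lower. With only the weaker peaks found in both replicates' lists, the calls of detoxification enzymes (odds ratio 1.45), histones (0.236) and major sperm proteins (0 of 31) were lost (Fisher exact tests, adjusted p = 0.127, 0.0575 and 0.0765). In the same exact tests 5 lists gained a call, which were neuron markers (odds ratio 5.35, adjusted p = 0.0236), body muscle markers (7.48, 0.0499), ribosomal proteins (4.08, 0.0252) and vacuolar ATPase (3.74, 0.0499) as higher and F-box A proteins (0.371, 0.00856) as lower. Among genes with any pooled peak in the window, 11.5% of those of detoxification enzymes were thresholded, against 32.9% of other genes (Fisher exact test, adjusted p = 0.00443); for fatty acid metabolism (19.4% against 32.8%) and nuclear hormone receptors (23.8% against 32.9%) this difference did not pass (adjusted p = 0.236 for both).

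No biological explanation was tested for the excess of these 3 lists, and with the GC content of the promoter window in a logistic model the odds ratios were 2.28 for fatty acid metabolism, 1.55 for nuclear hormone receptors and 1.60 for detoxification enzymes, all past the threshold (highest adjusted p 0.0235), while that of histones moved from 0.211 to 0.136, which argues against GC content as the whole cause. The upstream length in classes gave shares of 14.7 to 24.2%. In a logistic model these classes moved the odds ratio of translation factors from 3.19 to 2.84, and that call ended (adjusted p = 0.0710, n = 18319 genes). Those of fatty acid metabolism and nuclear hormone receptors were 2.22 and 1.54 in the same model (adjusted p = 0.00390 and 0.0147, n = 18319 genes). With only the weaker peaks found in both replicates' lists they were 2.70 and 1.66 (Fisher exact tests, adjusted p = 0.000937 and 0.0117). For these 2 lists this argues against length and against regions found in a single replicate as the whole cause. For detoxification enzymes the length classes moved the odds ratio from 1.52 (interval 1.09 to 2.13) to 1.46 (interval 1.04 to 2.04), and a call that stood just past the threshold ended (adjusted p = 0.0710, n = 18319 genes). With only the peaks found in both lists it was 1.45 (Fisher exact test, adjusted p = 0.127, 29 of 179 genes), so for these enzymes neither length nor regions found in a single replicate can be told apart as a cause with so few genes. Regions that bind many proteins, or any tag, stay open for all 3 lists, as no control ChIP was used here.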

How the results depend on the processing

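The depth of the libraries is unknown, so what it limits could not be measured. Over the alternatives, 83 values of the main results kept their direction and side of the threshold, or stayed within their interval or 1.5 times the count, and 8 did not; the promoter share ranged from 38.4 to 61.5%. Left out of these counts are 3 settings that moved little: the strongest peaks of the pooled list, which are the thresholded peaks in another order (motif values, for which flank sides changed, are counted), the middle of the peak, which differed from the summit at 62 peaks, and the log length of the upstream space as a straight line. That length was unrelated to weaker peaks at genes without a thresholded one (n = 18319 genes, likelihood ratio p = 0.250). For thresholded peaks it gave major sperm proteins a lower call that the Fisher exact test lacked. The logistic model without a covariate gave that call too (adjusted p = 0.0419 with the length and 0.0411 without, n = 19973 genes). The share found in both replicates was 99.3% with the full lists and 98.7% among the stronger 1359 peaks. With 1359 peaks of each replicate the shorter lists cap that share: each replicate alone held 49.8 and 49.9%, and both held 37.8%. Results without replicate 1 and without replicate 2 gave promoter shares of 47.55 and 46.8%. Ranking by q value was not run, because 1675 peaks shared the highest value. No paired analysis was possible because there is only 1 group. The GC alternatives, the logistic model without a covariate, the classes of upstream length and the summits outside promoters were chosen after seeing the data. Among single classes, lists and motifs, 383 values kept their side, 27 lost their call, 16 gained one and 31 turned.

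The other 5 were counts: chromosomes with an excess of peaks fell from 4 to 2, and tissue lists called from 1 to 0, with the stronger 1359 peaks. Tissue lists rose to 2 with the wider window. Against windows of the nearest GC content motifs called lower fell from 6 to 2 and 6-mers called higher from 750 to 280. The cause was not tested.

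Introns, below random over all summits, held 38.8% of those outside promoters and were not below random there, since promoters no longer take part of the total. Other directions turned as follows, and the cause was not tested. Chromosome II, at 16.6% of peaks, was called above its length and was below its share of genes. With GC content in the model or matched, odds ratios or ratios were 0.341 for histones, 1.00 for fatty acid metabolism, 1.34 for TGATAA, 1.34 for the PHA-4 site, 1.02 for runs of T and 0.813 for RGGTCA. The rest passed the threshold in neither setting. With the stronger peaks, intergenic summits were 22.1%. There odds ratios were 0 for neuron, 1.39 for germline, 1.42 for fatty acid and 0.904 for histone genes, and the GATA core ratio was 0.908. With 1 replicate's list (without replicate 1 or 2), odds ratios ranged from 0.762 to 1.59 for germline, 0.918 to 1.09 for nuclear hormone receptors and 0.757 to 1.36 for fatty acid genes, and ratios from 0.939 to 1.03 for the GATA core and 0.972 to 1.39 for AP-1. With the wider window they were 1.104 for germline, 1.84 for fatty acid and 0.832 for histone genes, with classes of upstream length 0.924 for histones, and with nearest starts 1.02 for fatty acid, 1.07 for nuclear hormone receptor and 1.05 for other transcription factor genes. GATA core ratios were 0.989 within 100 bp and 0.979 within 25 bp, where the CRE stood at 1. Between the stronger and weaker 1359 peaks, forkhead and SKN-1 shares differed by 0.0736 and 0.294 percentage points.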

Other observations

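The GC test of ribosomal protein genes, the comparison of summits inside and outside promoters for GACGCAG and that of GACGCAG at ribosomal protein genes were chosen after the values were seen. Of 18 sls-2 genes, which encode the SL2 RNA, 6 had a thresholded summit within 500 bp (33.3%, interval 13.3 to 59.0), and of 111 other snRNA genes 5 had one (4.50%, interval 1.48 to 10.2). These genes were picked because they held the strongest snRNA peaks, so a test on the same peaks would restate that choice and none is given. Several protein-coding and noncoding genes shared their peaks: mir-5549 lay beside the summit upstream of eef-1A.1 and rfc-4 (III, 6972111), linc-78 beside that of rpl-11.2, and linc-108 beside a summit on V at 15566665 (signal 203) whose nearest coding gene was acs-2, an acyl-CoA synthetase gene.

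The peaks at ribosomal protein promoters may reflect technical features of these genes. With the GC content of the promoter window in a logistic model, the odds ratio was 38.02 (n = 19973 genes, adjusted p = 2.33e-48), which argues against GC content as the whole cause. Signal over the body of highly transcribed genes would put summits there, and the density of summits per kb in the bodies was 0.0789 of that in the promoter windows, from 1 summit in 19.6 kb against 61 in 94.2 kb. The exact interval of this ratio, 0.00196 to 0.456, reaches past the bound of 0.2 set before the test, so signal over gene bodies cannot be told apart with so few bases outside promoter windows. Whether other tagged proteins or untagged animals give the same peaks was not tested, and neither was any biological explanation.

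A hypothesis is that the sequence GACGCAG, rather than RGGTCA, marks some of the regions with peaks. Its share at summits was 5.56 times that of windows of the nearest GC content, which were not matched on genomic class. Among the 1892 summit windows without GAGAGA its share was 8.25%, below the 11.03% of all summits. That was still 18.7 times the 0.441% of all flank windows, which were not matched on GC content. Taken singly, neither GC content nor overlap with GAGA repeats is therefore likely to be the whole cause. Summits outside the windows of annotated gene starts held it 0.916 times as often as those inside (interval 0.740 to 1.13). This argues against a sequence of those windows alone as the whole cause. Starts of other transcripts of coding genes, whose windows raised the promoter share to 55.5%, and promoters of other genes stay open. Counted per gene over the promoter window rather than at summits, GACGCAG was rarer at ribosomal protein genes with a peak (5 of 64, 7.81%). Other genes with a peak held it at 24.7% (Fisher exact test, p = 0.000925) and genes without a peak at 10.3%. The sequence may therefore not account for the peaks at ribosomal protein genes. Binding of NHR-11 itself to this sequence and indirect recruitment remain open, and no biological explanation was tested.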
